A study of Mus musculus with 6 samples.

How the data were processed

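RNA was sequenced from naive CD4 T cells of C57BL/6 mice, 3 libraries from wild-type littermates and 3 from mice whose cells lacked Trim28. Trim28 encodes a corepressor that zinc finger proteins bring to DNA, where it recruits the histone methyltransferase Setdb1. Per the labels' protocols, cells were enriched with magnetic beads and then sorted by flow cytometry, lysed in Trizol, and RNA was purified on columns and treated with DNase. Libraries were read as 100 bp pairs on a HiSeq2500, per the labels' protocols. Whether the library kit keeps the strand is not given in the sources used here, so reads from a gene and an antisense partner cannot be told apart. The title of the series also names stimulated cells, which are not analysed here.

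Per the submitters' processing notes, STAR, HTSeq, DESeq2 and the mm10 build were used, with no versions or roles given. The authors deposited 1 table of 19048 rows and 6 columns whose values are on a log10 scale. The scale was found from the values. With the deposited value turned back as 10 to its power minus 1, 100% of the values of each library were whole multiples of a single step per library, within 0.01 of a whole number. Read on a log2 or natural log scale, at most 17.8% were. The step is the worth of 1 read, so each value is the log10 of 1 plus a read count divided by a size factor. Median-of-ratios size factors recomputed from the recovered reads matched the steps in all 6 libraries. Depth, as the sum of recovered reads over the rows, ran from 22005759 to 44372701 reads. Counting intervals given below cover counting error only, since reads were pooled over the 3 libraries of a group. They leave out the spread between libraries. Reads made by PCR are not independent molecules, so even the counting error may be understated.

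Rows carry RefSeq transcript accessions, 16827 of messenger RNAs and 2221 of non-coding RNAs. A RefSeq gene table of the GRCm38.p6 assembly, the assembly of mm10, named 18811 rows. GENCODE release M21 metadata named a further 104 rows, and 133 rows holding 2.70% of the values stayed without a symbol. The rows named 16911 symbols, of which 1632 had several rows. For those, the row with the highest total stands for the gene and the others were tested as rows of their own. How reads shared by transcripts of 1 gene or by near-identical genes were assigned is not given in the sources used here. Values of close paralogs, such as Vmn2r96 and Vmn2r97, Zfp52 and Zfp53, the Gstt genes, the Gimap genes, the Ms4a genes, and Hspa1a and Hspa1b, are therefore uncertain.

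The main test was limma 3.58.1 in R 4.3.3, fitted on log2 of the normalized read count plus a pseudocount of 1, with the empirical Bayes trend. The fit took all 6 libraries with no covariate. Rows with a mean of at least 10 over the 6 libraries were tested, and a row was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Fold changes are on the log2 scale with the pseudocount, which understates the change of low genes. The negative binomial models planned as alternatives on recovered reads, edgeR and DESeq2, were not run. In their place, limma's voom weights were used on those reads and called 160 rows. The labels do not say whether the libraries came from separate mice, so p-values measure the spread between these libraries.

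Before the data were examined, 51 gene lists were fixed, covering Trim28 and its partners, gene families, T cell states, signalling, metabolism, stress, and markers of other cell types and of sex. For 3 lists, the name pattern used matched no symbol in the table, and other names of those genes were not searched. These were replication-dependent histones, genes of the mitochondrial genome and T cell receptor variable segments. Of the 51 lists, 46 had at least 5 tested rows. Those were tested with camera from limma, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. Estimated correlations and the fry test were alternatives. The rule for named genes was also fixed before the data were examined. It took Trim28, then the 12 largest rises and the 12 largest falls among called genes whose groups did not overlap, with a mean of at least 50 in the higher group and a proper symbol. It then took up to 4 members with the smallest p from each list described, and markers of other cell types and sex-linked genes whatever their p. Not every gene this rule took is reported here. Where wild-type libraries held 0 reads of a gene in all, the fold is a lower bound computed against 3 reads over the group. Where they held 1 to 3 reads, the fold is given with a 95% exact binomial interval.

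Other settings were the pseudocount, the filter, 3 other scalings, the variance model, a replicate block, leaving out each library, and stricter thresholds. Chosen after the data were seen were limma's voom weights on recovered reads, Y-linked transcripts as a covariate, only libraries with nearly no Y-linked transcripts, rows summed per gene, and array weights. No pair of libraries of the same group agreed within sampling noise, since the chi-square per degree of freedom was at least 18.0 in every pair. Neighbouring genes were compared with 10000 random sets of tested genes matched on mean value. Transcript lengths and strands came from GENCODE M21. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

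The scripts were tested on simulated data. Counts were drawn from the real means and library sizes, with 200 rows changed, and 12860 rows passed the filter. At a 2-fold change 69 of 100 changed rows were recovered, and at a 4-fold change 89 of 100, all in the right direction, with 1 call among unchanged rows. Each library was drawn independently, with dispersions smoothed over the mean and no library standing apart. These rates may not hold for the real data, where a knockout library stood apart, as given below. In a second simulation, a list raised by 0.4 on the log2 scale was called by camera and 0 other lists were, with simulated genes that varied independently. The neighbour count gave a p under 0.05 for 2.5% of 200 random sets drawn from 11940 genes. Those sets were drawn in the same way as the random sets they were compared with. A small share was therefore fixed beforehand and says nothing on whether matching on mean value is enough. The neighbour count gave a permutation p of 0.0001 for a set with 16 planted pairs.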

Results

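Messenger and non-coding RNA of naive CD4 T cells, the helper T cells that have not yet met antigen, was measured in 3 wild-type libraries (WT1 to WT3) and 3 TRIM28 knockout libraries (KO1 to KO3). The table gives normalized read counts for 19048 transcript rows. The depth was 23438722, 29687968 and 40586195 reads in WT1, WT2 and WT3, and 44372701, 22005759 and 36810371 in KO1, KO2 and KO3. Between 83.2% and 92.4% of the rows were above 0, the highest share being in KO3. The comparison asks which transcripts differ in resting naive cells when Trim28 is missing.

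Trim28 itself (row NM_011588, chromosome 7, positions 13024152 to 13031032 of mm10) was measured first, as a check of the labels. Its normalized read count was 8429, 8287 and 9428 in the wild-type libraries, and 738, 628 and 1247 in the knockout libraries. The knockout mean was 9.99% of the wild-type mean, and the share was 14.3% in KO3 against 8.46% in KO1 and 7.21% in KO2. The log2 fold change was -3.38 (SE 0.22, n = 3 per group), with an adjusted p of 0.000135 in limma. An exact two-sided permutation test gave p = 0.1, the smallest that 3 libraries against 3 allow. Which part of the gene is removed in these mice is not given in the sources used here.

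**Figure D1:**
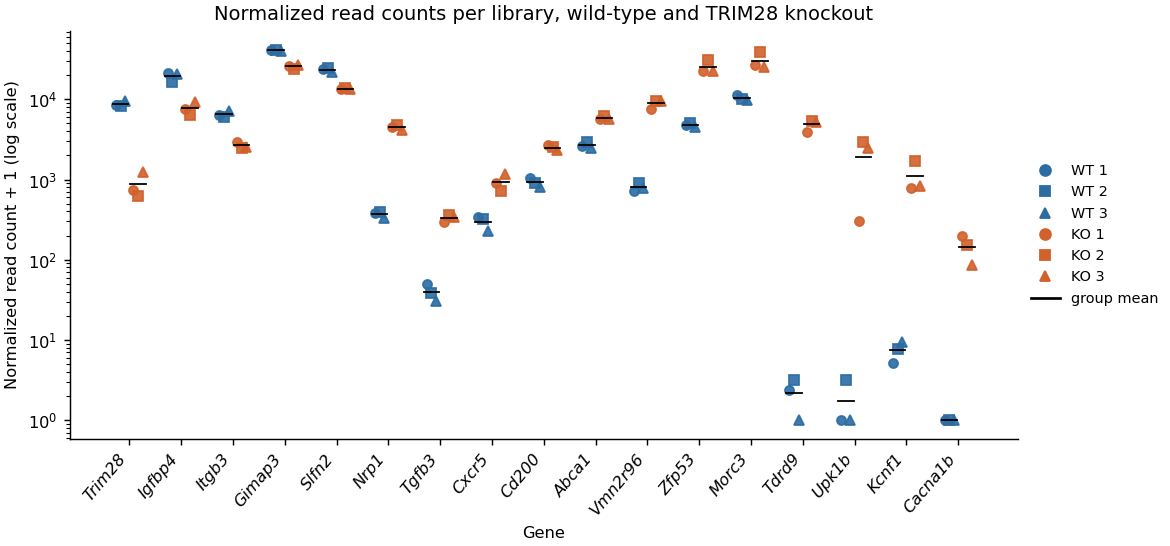
Normalized read count plus 1 on a log axis for 17 genes, with 1 point per library (blue for wild-type, orange for knockout, shape for the replicate number) and a black line at each group mean. Trim28 lies between 628 and 1247 in the knockout libraries against 8287 or more in the wild-type libraries, and Tdrd9 lies at 2.20 or below in every wild-type library and at 3944 or above in every knockout library.

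Naive CD4 T cells without Trim28 gained more transcripts than they lost. Of 13022 rows tested, from 12030 genes, 155 rows rose and 41 fell in limma, Trim28 included, which is 79.1% rises. The rises were also larger. Their median log2 fold change was 1.76, and 119 rows rose by at least 2-fold, 67 by at least 4-fold and 25 by at least 16-fold in the fit. Of the falls, 13 reached 2-fold and 2 reached 4-fold, which were Trim28 and Hspa1a, and their median was -0.80. The 3 knockout values lay apart from the 3 wild-type values in each of the 196 called rows, and in 18.8% of all tested rows, against 10% by chance. The median log2 fold change over all tested rows was 0.0019. An unadjusted p under 0.05 was reached by 1651 rows. Among the libraries with at most 2.39 normalized Y-linked reads (2 against 2), 37 rows were called, 36 of them rises, and with Y-linked transcripts as a covariate 169 were, 139 of them rises, both chosen after the data were seen. The count went to 553 without KO3, with 195 of the 196 among them, and the share of rises was lower there (354 rows, 64.0%). KO3 itself lay on the knockout side of the midpoint between the other libraries' group means in 299 of the 553 rows (54.1%). The count went to 124 without WT1, 127 without WT3 and 113 without KO2. Falls numbered 14 without WT1, 18 without WT2, 14 without WT3, 22 without KO1, 19 without KO2 and 199 without KO3. Without the mean-variance trend 124 rows were called, 17 of them falls. Hspa1a, Igfbp4 and Itgb3 were among the falls not called in those 4 libraries.

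**Figure D2:**
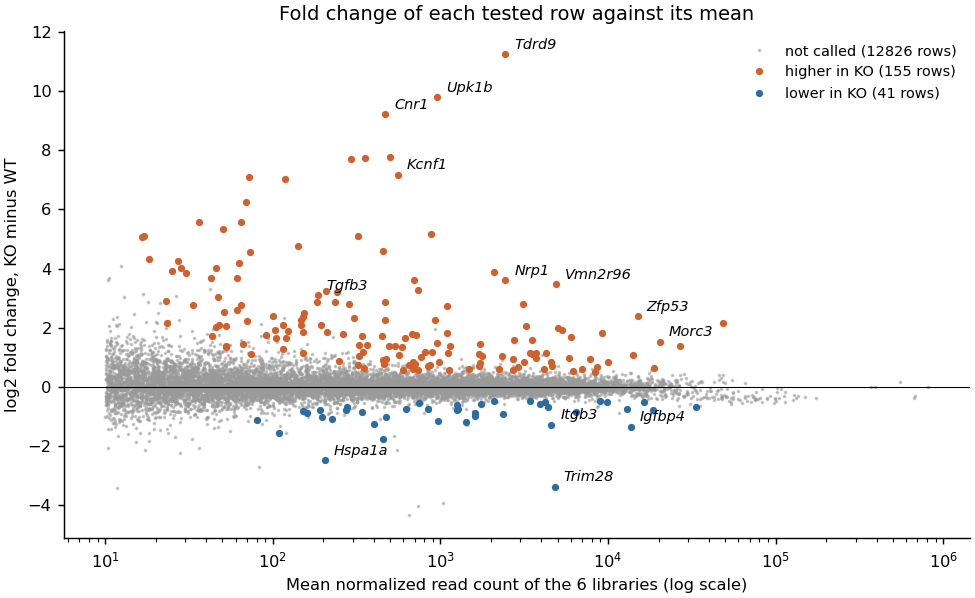
Log2 fold change (knockout minus wild-type) of each of the 13022 tested rows against its mean normalized read count over the 6 libraries on a log axis, with the 155 rises in orange and the 41 falls in blue. The rises reach 11.25 for Tdrd9, while the lowest fall is Trim28 at -3.38.

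The 12 largest rises were in genes with wild-type means of 6.43 or below, which a ranking by fold change favours. Of all 155 rises, 29 had a wild-type mean under 10. Tdrd9, a helicase of the small RNA pathway that protects germ cells from transposons (chromosome 12, 111971488 to 112068854), had 3 reads over the wild-type libraries and 15816 over the knockout libraries, a ratio of 4608 (95% interval 1580 to 22300). Upk1b, a membrane protein of the bladder lining, had 2 wild-type reads and a ratio of 2437 (674 to 20100). Its knockout values were uneven, at 300 in KO1 against 2970 in KO2 and 2486 in KO3. Cnr1, the cannabinoid receptor of the brain, had 1 wild-type read and a ratio of 2252 (404 to 89000). It too was uneven in the knockout, at 278 in KO1, 1752 in KO2 and 786 in KO3. Cacna1b, the pore subunit of a neuronal calcium channel, had no wild-type read and was at least 142-fold higher. Lix1, Cbr3 (a carbonyl reductase), Ryr2 (the calcium release channel of heart muscle) and Kcnf1 (a potassium channel subunit) rose by 7.17 to 7.76 on the log2 scale. Lix1 and Cbr3 were highest in KO2, at 1890 and 1570, against 453 and 237 in KO1 and 660 and 323 in KO3. Kcnf1 went from 6.43 ± 2.16 to 1108 ± 514 (SD, n = 3 per group). The glutathione transferase Gstt1, with 3 wild-type reads, had a ratio of 235 (80.1 to 1140), Prr5, also with 3, a ratio of 132 (44.8 to 641), and Cthrc1, with 1, a ratio of 180 (32 to 7150). Wfdc2 completed the 12, at a log2 fold change of 5.56. Lix1, Cbr3, Upk1b and Cnr1 were not called with voom weights, at adjusted p from 0.141 to 0.362, and Wfdc2 was not called without KO1 or without KO2.

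The 12 largest falls other than Trim28 were smaller than these rises. The rule for named genes required a wild-type mean of at least 50 for a fall, so their expression in wild-type cells follows from that rule. Hspa1a, an inducible heat shock protein, fell from 345 ± 71.3 to 61.6 ± 20.6 (SD, n = 3 per group), a log2 fold change of -2.49 (SE 0.26, limma adjusted p 0.00168). Igfbp4, which encodes an insulin-like growth factor binding protein, fell from 19669 ± 2604 to 7747 ± 1393, and Itgb3, an integrin subunit, from 6519 ± 588 to 2662 ± 249. The myosin Myo10 fell from 1969 ± 115 to 868 ± 112 and the cadherin Cdh24 from 569 ± 76.0 to 237 ± 36.9. Ms4a6d and Ms4a4c, of the Ms4a family of membrane proteins, fell by 1.56 and 0.99 on the log2 scale. Bbc3, a trigger of apoptosis, fell by 1.15. The remaining genes were Marveld2, Raph1, Card19 and Tnfrsf25, a receptor of the tumor necrosis factor family, with log2 fold changes between -1.11 and -1.02. Tnfrsf25 had 2 rows, of which the one with the highest total is given, and it was not called with rows summed per gene. Each of Ms4a6d, Bbc3, Marveld2, Raph1, Card19 and Tnfrsf25 lost its call without WT1, without WT2 and without WT3, and Ms4a4c without WT1 and without WT3. Without KO1, Bbc3, Marveld2, Raph1, Tnfrsf25 and Ms4a4c lost theirs, and without KO2, Marveld2, Raph1, Card19, Tnfrsf25 and Ms4a4c did. The direction stayed in each case, which was fixed beforehand, since the groups lay apart in every called row.

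Among Trim28 and its partners, 31 genes were tested, of which 3 rose, Trim28 fell and 27 did not pass. Resf1, which acts with Setdb1 in silencing retroelements, rose from 101 ± 11.4 to 512 ± 124 (SD, n = 3 per group; log2 fold change 2.31, SE 0.20). Morc3, a chromatin ATPase, rose from 10411 ± 847 to 30359 ± 7053, and Trim24, a relative of Trim28, from 8.49 ± 2.37 to 85.0 ± 42.6. Trim24 was not called without WT2, WT3, KO1 or KO2. Adjusted over the list alone, 5 rose and 1 fell. Camera did not call the list (adjusted p 0.0502), and without KO3 it did (adjusted p 0.0365; adjusted p = 0.544 with an estimated correlation).

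The list of zinc finger genes with a Zfp, Zscan, Zkscan or related name, many of which encode DNA-binding proteins that recruit Trim28, gave 9 rises and 0 falls among 326 tested in limma, with 48 at an unadjusted p under 0.05. Adjusted over the list alone the counts were again 9 and 0, and without KO3 they were 16 and 0. All 9 rises had the Zfp name, and 7 lay on chromosome 17. Zfp53 rose from 4782 ± 254 to 25233 ± 4803 (SD, n = 3 per group; log2 fold change 2.38, SE 0.13), Zfp760 from 319 ± 90.4 to 1547 ± 540, Zfp820 from 30.4 ± 0.63 to 171 ± 48.3 and Zfp52 from 1073 ± 81.3 to 2343 ± 234. The list's median log2 fold change was 0.07, and 0.13 without KO3, and camera called it as higher (adjusted p 0.00673), but not with an estimated correlation (adjusted p = 0.711 with an estimated correlation). Under quantile normalization the median over all tested rows was -0.039. No called row changed sign under any of the 3 other scalings. The smallest called change was 0.48 on the log2 scale, so the kept signs do not bear on the list's median.

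Olfactory and vomeronasal receptor genes, which encode the receptors of sensory neurons in the nose, had 13 tested members, of which 2 rose and 11 did not pass. Vmn2r96 rose from 805 ± 101 to 8915 ± 1126 (SD, n = 3 per group; log2 fold change 3.47, SE 0.13) and Vmn2r97 from 295 ± 40.7 to 772 ± 56.1. Vmn2r99 went from 4.66 to 48.5 without passing (limma adjusted p 0.0541), as did Vmn1r32, at 3.57 and 17.6. Adjusted over the list alone, 6 rose and 1 fell. Camera called the list as higher (adjusted p 1.42e-05; adjusted p = 0.3 with an estimated correlation). Tdrd9 was the only member of 16 tested germline and 2-cell embryo genes to change in limma, where 2 had an unadjusted p under 0.05. None of 21 imprinted genes was called in limma and 1 had an unadjusted p under 0.05, and Igf2r had the smallest p, with a log2 fold change of 0.22 (SE 0.09). Among 13 clustered protocadherin genes limma called 0, with 0 at an unadjusted p under 0.05, and their median log2 fold change was 0.34. Camera called none of these 3 lists.

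**Figure D3:**
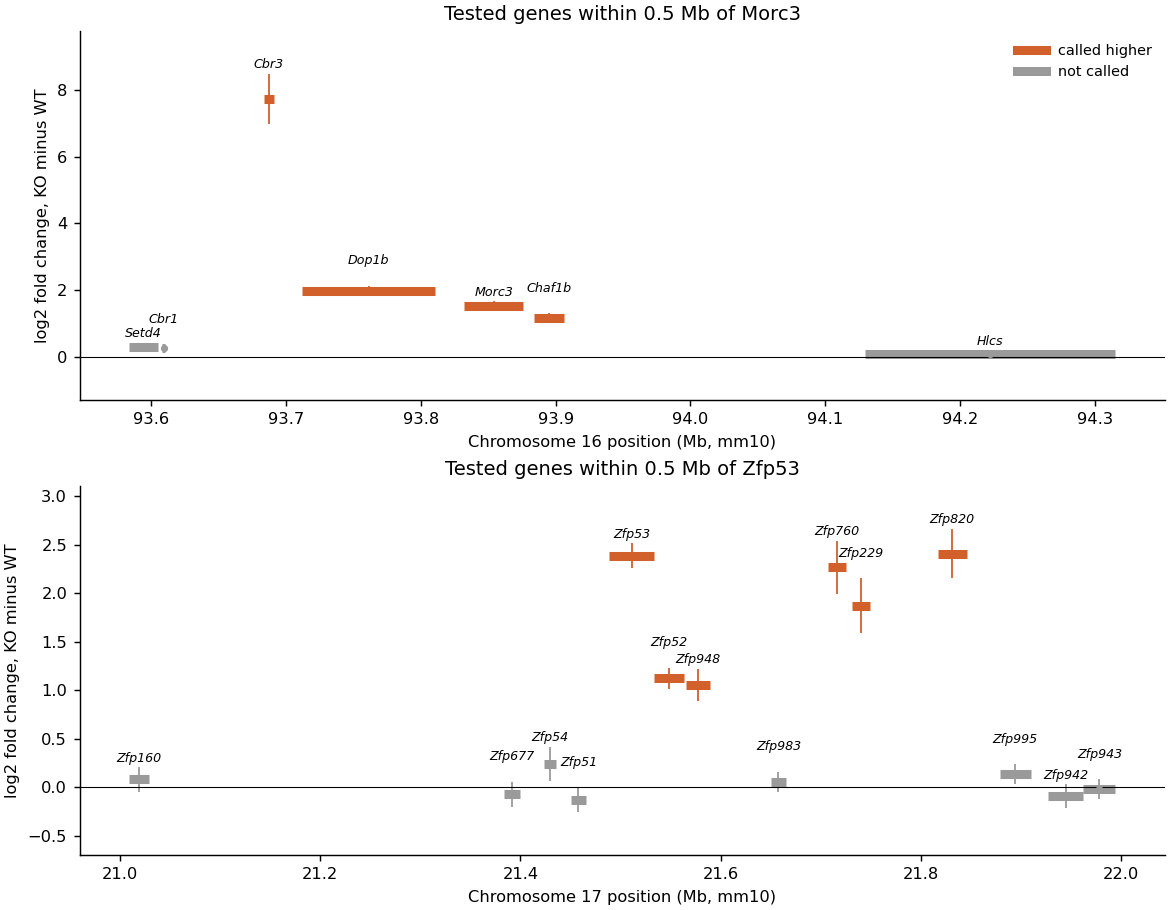
Log2 fold change (knockout minus wild-type) of tested genes against their position on chromosomes 16 and 17 of mm10, within 0.5 Mb of Morc3 and of Zfp53. Thick bars span each gene, thin bars are ± 1 SE, orange marks called rises and grey marks genes not called. Around Morc3 the 4 rises Cbr3, Dop1b, Morc3 and Chaf1b stand side by side, and around Zfp53 the rises stand in 2 groups of 3 with Zfp983, near 0, between them.

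Nrp1, Il2ra and Cd200 were the genes that rose in the lists of regulatory T cells and of inhibitory receptors and anergy. Nrp1, a co-receptor for semaphorins that also marks regulatory T cells made in the thymus (chromosome 8), had the smallest p of all tested rows. It rose from 370 ± 32.6 to 4496 ± 332 (SD, n = 3 per group), a log2 fold change of 3.60 (SE 0.11, limma adjusted p 1.42e-06). Il2ra, the alpha chain of the interleukin-2 receptor, rose from a mean of 170 to a mean of 482, with its highest value, 714, in KO3. It lost its call without WT1, WT2, WT3 or KO2. These were the 2 called among 26 tested genes of the regulatory T cell list, with 24 not passing and 4 rises when adjusted over the list alone. Ikzf4 (155 and 364 in the group means) and Ctla4 (log2 fold change 0.51, SE 0.17) were among those that did not pass. The list's median was 0.52, and 0.20 without KO3, and camera called it as higher (adjusted p 1.76e-06; adjusted p = 0.634 with an estimated correlation). Of 23 genes of the inhibitory receptor and anergy list, Nrp1 and Cd200 rose and 21 did not pass, with 3 rises over the list alone. Cd200, a ligand that restrains myeloid cells, rose from 919 ± 126 to 2505 ± 192. Camera called that list too (median 0.33, adjusted p 6.39e-05; adjusted p = 0.32 with an estimated correlation).

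Of 17 genes of follicular helper T cells, 2 rose and 15 did not pass, and 3 rose over the list alone. Cxcr5, the receptor that leads cells into B cell follicles, rose from 294 ± 58.9 to 926 ± 227 (SD, n = 3 per group; log2 fold change 1.64, SE 0.21), and Cd200 was the other. Without KO3, 1 gene of that list also fell. Pou2af1 (526 and 774) and Bcl6 (831 and 1152) did not pass. The list's median was 0.25 (camera adjusted p 0.000318; adjusted p = 0.459 with an estimated correlation). Among 36 T cell activation genes, 4 rose and 32 did not pass, and 6 rose and 1 fell over the list alone. The 4 were Cd200, Il2ra, Tnfrsf1b, a tumor necrosis factor receptor (2142 ± 131 to 4708 ± 410), and Traf1, an adaptor of such receptors (3564 ± 316 to 5751 ± 751). Traf1 was not called without WT1, WT3 or KO1. The activation list had a median of 0.25, and 0.09 without KO3, where camera no longer called it (adjusted p 0.000501 with all libraries, 0.0571 without KO3; adjusted p = 0.634 with an estimated correlation).

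Of 20 Th1 genes limma called 0 and 3 had an unadjusted p under 0.05, with Ifngr1 at 6680 and 9064 in the group means. Camera called the list (median 0.31, adjusted p 0.0301; adjusted p = 0.634 with an estimated correlation) but not without KO3 (median 0.14, adjusted p 0.404). Neither the 13 Th2 genes, the 15 Th17 genes nor the 52 effector and memory genes held a limma call, with 4, 2 and 11 at an unadjusted p under 0.05, and camera called none of these lists. Over the lists alone, Th2 genes gave 1 fall and the others none. Without KO3, 1 Th2 gene rose, and 1 Th2, 1 Th17 and 3 effector and memory genes fell. Among 26 genes of the transforming growth factor beta pathway, Tgfb3, a secreted ligand, rose from 38.5 ± 9.77 to 331 ± 33.7 (SD, n = 3 per group; log2 fold change 3.10, SE 0.22) and 25 did not pass. Without KO3, 2 genes of that pathway rose and 2 fell, and without KO2, 2 rose. Lrrc32, which holds such ligands on the cell surface, went from 25.1 to 145 without passing (limma adjusted p 0.151).

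Of 31 naive T cell genes, Igfbp4 and Dapl1 fell and 29 did not pass, and 5 fell over the list alone. Dapl1 went from 5396 ± 665 to 3369 ± 292 (SD, n = 3 per group) and lost its call without WT1, WT3, KO1 or KO2. Il7r, the interleukin-7 receptor, was at 37156 and 24797 in the group means, without passing. The list was called as lower (median -0.10, camera adjusted p 0.0103; adjusted p = 0.459 with an estimated correlation) but not without KO3 (adjusted p 0.299). The Gimap genes, small GTPases that support lymphocyte survival, had 1 fall among 7 tested and 3 over the list alone. Gimap3 fell from 41006 ± 445 to 25713 ± 1380 (log2 fold change -0.67, SE 0.08), and without KO3 2 Gimap genes fell. Gimap6 was at 40754 and 31554 without passing. The list's median was -0.26 (camera adjusted p 0.000318; adjusted p = 0.459 with an estimated correlation). Slfn2, which keeps T cells quiescent, was the only one of 8 Schlafen genes called, falling from 23517 ± 1266 to 13548 ± 284. Over that list alone 1 also fell, and camera did not call it.

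Among 25 chemokine receptor and migration genes, Cxcr5 rose and Gpr183, an oxysterol receptor that guides lymphocytes, fell from 10440 ± 498 to 7501 ± 430 (SD, n = 3 per group). Among 38 cytokine receptor and JAK-STAT genes, Il2ra rose and Il27ra, a receptor subunit for interleukin-27, fell from 11672 ± 192 to 8081 ± 560. Gpr183 lost its call without WT1, WT2, WT3, KO1 or KO2, and Il27ra without WT1, WT2, WT3 or KO2. In the cholesterol list of 26 genes, Abca1, the cholesterol exporter, rose from 2659 ± 251 to 5894 ± 292, and Insig1, which restrains cholesterol synthesis, fell from 2440 ± 93.2 to 1735 ± 153. Insig1 lost its call without WT1, WT2, WT3, KO1 or KO2. The synthesis enzymes Sqle (1061 and 677) and Fdft1 (965 and 785) did not pass. Adjusted over each list alone, migration genes gave 2 rises and 3 falls, cytokine receptors 3 and 3, and cholesterol genes 1 and 2. Camera called none of these 3 lists.

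Of 87 cytosolic ribosomal protein genes, 0 were called over all rows in limma and 72 had an unadjusted p under 0.05. Over the list alone, 71 fell and 1 rose. Their median log2 fold change was -0.38, and camera called the list as lower (adjusted p 4.69e-30; adjusted p = 0.459 with an estimated correlation). Rplp1 was at 118410 ± 7432 and 83836 ± 4780, and Rps2 at 61191 ± 5537 and 43424 ± 3673 (SD, n = 3 per group). These genes took 13.65%, 13.42% and 12.62% of the normalized counts in WT1, WT2 and WT3, and 9.085%, 10.9% and 11.34% in KO1, KO2 and KO3. Without KO3 their median was -0.40 and 12 fell. Of 37 ribosome biogenesis genes and 75 respiratory chain genes limma called 0, with 9 and 5 at an unadjusted p under 0.05. Without KO3, 1 and 2 of them fell. Their medians were -0.14 and -0.14, and camera called both as lower (adjusted p 0.000486 and 3.55e-06; adjusted p = 0.3 and 0.711 with an estimated correlation).

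Interferon-stimulated genes went both ways, with 1 rise, 1 fall and 68 of 70 not passing. Usp18, a protease that dampens interferon receptor signalling, rose from 2496 ± 28.4 to 4914 ± 134 (SD, n = 3 per group), and Ifi44 fell from 435 ± 13.4 to 242 ± 6.60. Without KO3, 2 rose and 6 fell, and the list's median was -0.15. Over the list alone, 3 rose and 3 fell, and camera called the list as lower (median -0.10, adjusted p 0.0182; adjusted p = 0.657 with an estimated correlation). Heat shock and dissociation stress genes held 1 fall, Hspa1a, among 23 tested, and 1 rise and 5 falls over the list alone. Hspa1b was at 874 and 227 without passing (limma adjusted p 0.0616). Without KO3 the heat shock list held 2 rises and 2 falls, and without KO1 2 falls. Of 35 immediate early genes limma called 0, with 10 at an unadjusted p under 0.05, and 1 rose and 6 fell over the list alone. Without KO3, 7 immediate early genes fell, and without WT2, 1 did. Jun was at 15095 and 8023 and Fosb at 2006 and 871. Camera called both lists as lower (adjusted p 0.0133 and 0.0358; adjusted p = 0.459 and 0.711 with an estimated correlation), and the heat shock list not without KO3 (adjusted p 0.0619). Bbc3 was the only call among 33 apoptosis genes and among 30 p53 target genes. Eno2, a glycolytic enzyme, was the only call among 27 glycolysis genes, rising from 28.5 ± 1.41 to 76.3 ± 17.2, and lost its call when any of WT1, WT2, WT3, KO1 or KO2 was left out. T cell receptor signalling (44 genes), cell cycle (45), antigen presentation (23), nucleic acid sensing (19), mTORC1 and amino acid transport (24) and polymerase II pausing (29) held 0 limma calls, with 11, 2, 1, 0, 4 and 1 genes at an unadjusted p under 0.05. Adjusted over each list alone, apoptosis genes gave 1 fall, p53 targets 2 falls, glycolysis 2 rises and 1 fall, mTORC1 genes 1 fall, and the other 5 lists none. Camera called none of these 9 lists. Without KO3, limma gave 6 falls among cell cycle genes, 2 among apoptosis genes, 1 rise and 2 falls among p53 targets, 2 rises in glycolysis, 2 in T cell receptor signalling and 1 in polymerase II pausing. Camera then called the cell cycle and antigen presentation lists as lower (adjusted p 0.000188 and 0.0381; adjusted p = 0.544 with an estimated correlation for both). In all, camera called 15 of 46 lists, 7 as higher and 8 as lower, and 0 with an estimated correlation, where adjusted p ran from 0.3 to 0.983 and 4 lists had an unadjusted p under 0.05. With the preset correlation, splits of the libraries other than the real one called 11 to 19 lists, as given below.

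**Figure D4:**
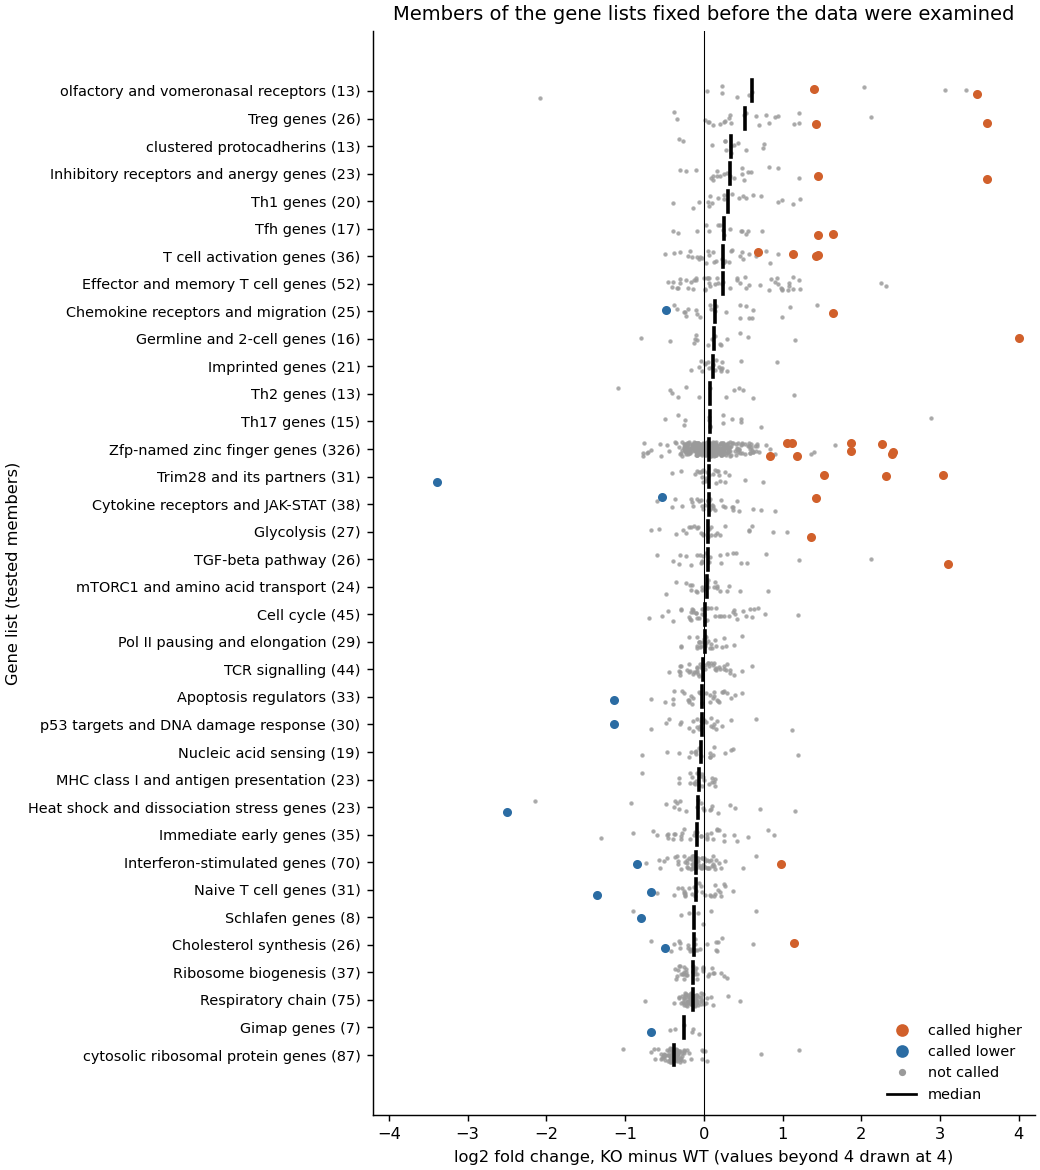
Log2 fold change (knockout minus wild-type) of each tested member of the gene lists, with 1 line per list ordered by its median (black bar), called rises in orange, called falls in blue and other members in grey; values beyond 4 are drawn at 4. Called members are few in every list, and most grey points of the ribosomal protein list lie left of 0 around its median of -0.38.

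Markers of other cell types set KO3 apart from the other libraries. All 16 tested B cell markers and all 6 gamma-delta T cell markers were highest in KO3, as were 10 of 13 markers of natural killer and innate lymphoid cells and 11 of 13 of monocytes and macrophages. Cd79b was at 634 in KO3 and between 46.6 and 87.8 elsewhere, Cd163l1 at 159 against 9.996 or less, and Cd8b1 at 4206 against 557 to 1032. Markers of dendritic cells and of erythroid cells and platelets were highest in KO3 for 9 of 11 and 9 of 10. Neutrophil markers were high in WT1 and WT3 too, with S100a8 at 311 in WT1, 88.1 in WT3, 96.4 in KO3 and 0 in the other libraries. Of 11 thymocyte and 8 CD8 T cell markers, 5 and 4 were highest in KO3. None of the markers was called between the groups in limma, with at most 3 per list at an unadjusted p under 0.05, and camera called none of the 9 lists tested. Without KO3, limma called 1 dendritic cell, 1 gamma-delta T cell, 1 monocyte and 2 thymocyte markers as lower, and camera called the lists of B cells, monocytes and neutrophils as lower (adjusted p 0.0201, 0.0381 and 0.0106; adjusted p = 0.567, 0.544 and 0.567 with an estimated correlation). Of 2 tested stromal and endothelial markers and the 1 gene tested as an immunoglobulin segment, Ighmbp2, which is named like one but encodes a helicase, none was called, and 0 had an unadjusted p under 0.05.

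**Figure D5:**
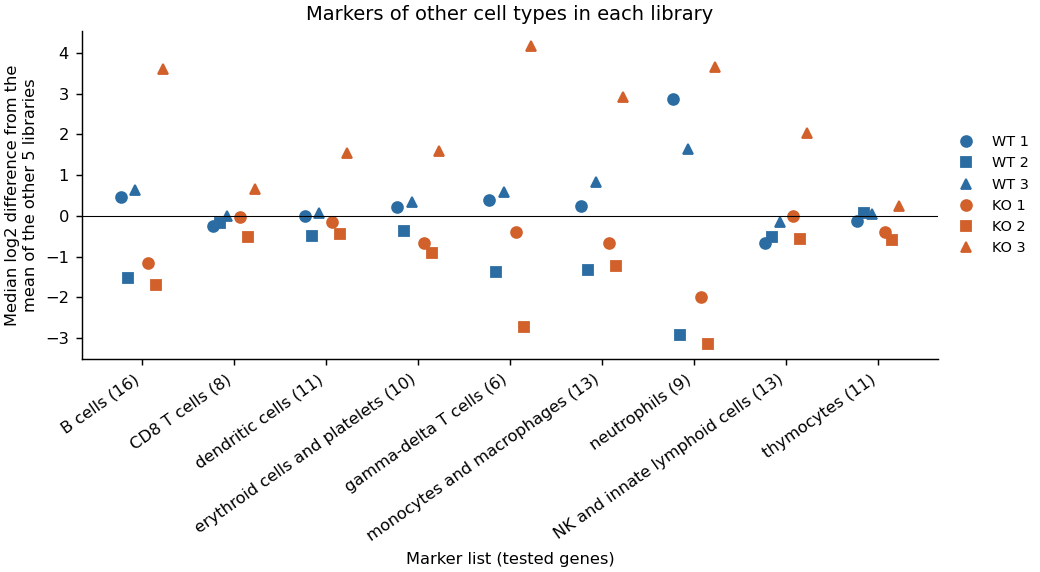
Median log2 difference of each library from the mean of the other 5 libraries, for 9 lists of markers of other cell types, with 1 point per library (blue for wild-type, orange for knockout, shape for the replicate number). KO3 is the highest library in each list and reaches 4.16 for gamma-delta T cell markers, and WT1 reaches 2.86 for neutrophil markers.

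Sex-linked transcripts did not follow the groups. Ddx3y was at 5801 in WT1 and 5422 in KO2 and at 0 in the other 4 libraries, and Eif2s3y at 3022 and 2307 in the same libraries and 0 elsewhere. Uty was at 1986 in WT1 and 2228 in KO2, at 0 in WT2, and at 0.772, 0.714 and 2.39 in WT3, KO1 and KO3. Xist, which is made from the inactive X chromosome of females, was present in all 6 libraries, at 12289 in WT1 and 16359 in KO2 against 19461 to 28062 in the others. None of the 5 sex-linked genes tested was called in limma, and 0 had an unadjusted p under 0.05.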

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

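Trim28 and all of the 196 called rows that could be refitted kept their direction under every alternative run. The groups lay apart in each of the 196 rows. Leaving out libraries or changing the pseudocount, filter or variance model therefore could not turn the direction, and the kept signs there are no support. Trim28 was called in each alternative (log2 fold change -3.67 to -3.18). Called rows numbered 197 and 195 with pseudocounts of 0.5 and 5, 198 with no filter, 186 at a mean of at least 50, 196, 199 and 195 under TMM, quantile and upper-quartile scaling, 212 with robust empirical Bayes, and 175 with the replicate block. Without the mean-variance trend 124 were called, 17 of them lower. An adjusted p under 0.01 left 111, and an absolute log2 fold change of at least 1 left 132. Leaving out 1 library gave 113 (without KO2) to 553 (without KO3) calls, 94 to 354 higher and 14 to 199 lower, with 12 to 21 lists. Of settings chosen after the data were seen, voom weights gave 160, Y-linked transcripts as a covariate 169, rows summed per gene 197, array weights 281 (76 lower), and only libraries with nearly no Y-linked transcripts 37 (36 higher, 1 lower) and 23 lists. Fewer libraries enter that last fit and the leave-one-out fits; otherwise the cause was not tested. Of the 15 lists, 0 were called with an estimated correlation and 3 with fry. Without KO3, the cell cycle and B cell marker lists reversed to lower (adjusted p 0.000188 and 0.0201), but not with an estimated correlation (adjusted p = 0.544 and 0.567 with an estimated correlation). With 1 library left out, adjusted p ran from 0.0001881 to 0.9852 for the cell cycle list and from 0.005238 (without KO2) to 0.9709 (without WT2) for the list of B cells. Deviations of wild-type and knockout libraries of the same number correlated at -0.312, 0.256 and 0.363, and not every library correlated best with its own number. With 3 libraries per group, these values cannot tell whether the numbers pair the libraries. The planned edgeR and DESeq2 fits were not run. Depth limits genes with few reads, where 29 of the 155 rises had a wild-type mean under 10.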

Other observations

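The tests of transcript length in their present form, of depth, of the library that stands apart and of other splits of the libraries were chosen after the result was seen.

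Genes that rose in the knockout often stood next to each other. Of 153 raised genes with a position, 32 had another raised gene within 100 kb, in 12 groups. On chromosome 16, from 93683219 to 93906115 of mm10, Cbr3, Dop1b, Morc3 and Chaf1b rose by 7.73, 1.99, 1.52 and 1.16 on the log2 scale, and they are the 4 tested genes there. On chromosome 10, from 75771233 to 75837419, Ddt and the glutathione transferase genes Gstt3, Gstt1 and Gstt2 rose by 1.39, 4.18, 7.02 and 1.80. On chromosome 8, Snai3 and its neighbour Rnf166 rose by 5.16 and 0.60, beside the non-coding Gm20735 and 9330133O14Rik at 5.34 and 1.33. Chromosome 17 held 2 groups of 3 zinc finger genes, Zfp53, Zfp52 and Zfp948, and Zfp760, Zfp229 and Zfp820, and between the groups Zfp983 was not called. Dop1b, Chaf1b, Ddt, Gstt2, Gstt3, Snai3, Rnf166, Gm20735, 9330133O14Rik, Zfp948, Zfp229 and Zfp983 were picked after their values were seen. Of 41 lowered genes, 40 entered this count, which took only rows that stand for a gene and have a position on an autosome or the X chromosome. Of these 40, 0 had another lowered gene within 100 kb, against a median of 0 in random sets.

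Random sets of genes matched on mean value gave a median of 8 raised genes with such a neighbour and at most 25 in 10000 draws, against 32 (permutation p = 0.0001, the smallest these draws can give), so random placement is argued against. Reads shared between paralogs would leave no excess of pairs with different names, yet 19 such pairs were found against at most 14 in the random sets. Shared reads from overlapping gene models are argued against too, since 6.9% of the 29 pairs overlap. Transcription that reads on into the next gene stays open, and other causes shared by neighbouring genes were not tested. Of 18 adjacent pairs, 77.8% lie on the same strand against 45.3% of all adjacent tested pairs, and 4 pairs lie on opposite strands. The share of 77.8% is above the central 95% of random draws at the rate of all pairs (22.2% to 66.7%). It is short of the 80% set beforehand for reading on. Some of the same-strand pairs join members of the same gene family, such as Gstt3 and Gstt1 or Zfp53 and Zfp52. The pairs used for comparison were not matched on family, so the excess cannot decide the question.

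Camera called the ribosomal protein list as lower (median -0.38), but not with an estimated correlation (adjusted p = 0.459 with an estimated correlation) and limma called 0 of its 87 genes, with 72 at an unadjusted p under 0.05. For 30 of the 87 rows, other rows within 25% of the length and a factor of 2 of the mean were at hand, and their median log2 fold change was -0.09 (bootstrap interval -0.11 to -0.04) against -0.36 for the ribosomal rows, so length bias is argued against for these. This match was set after a looser one had been seen, and for the other 57 rows, with a median of -0.39, too few matched rows exist, so length bias cannot be told apart there. With log2 depth as a covariate the median was -0.35 against -0.38, which argues against depth as the whole cause. A biological difference by genotype stays open, as does any difference in RNA quality, which was not tested.

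KO3 stood apart, with 167 rows at least 4 times higher than in any other library, against 3 or fewer such rows in each other library. Of these, 33 rows or 19.8% were fixed markers of other cell types, against 0.74% of tested rows, so cells of other types that passed the sort may be part of the cause. The most abundant marker was higher in KO3 than elsewhere for some lists (Car2 at 779 against at most 350, Mpo at 1737 against 227). For others it was not (Il7r at 19013 against 42275, Themis at 10955 against 15291, Ms4a6c at 1388 against 2009, Bst2 at 1724 against 1798). Il7r and Themis are also on the naive T cell list, and each of these 4 markers was at 1173 or more in every library. Their values therefore say little on cells of other types in KO3. For neutrophils, 4 of 9 markers were highest in KO3. A mislabelled wild-type library is argued against, since Trim28 was at 14.3% of the wild-type mean. What stays open is why the other 134 rows were high, and why KO3 lay on the knockout side in 54.1% of the 553 rows called without it, since rows chosen on the other libraries also tend to shrink in a library left out.

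All 10 splits of the 6 libraries into 3 and 3 were fitted. The real split called 196 rows and the highest of the others called 1, so 1 split of 10 reached the real count, and 10 splits are too few for a share under 0.05. For the gene lists, the real split called 15 with the preset correlation, and the others called 11 to 19. As many as 15 were called in 7 of the 10 splits, the real one included. The number of lists called with the preset correlation therefore does not set the real split apart from the others.

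WT1 and KO2 held both Y-linked transcripts and Xist, at the values given above, and the labels do not give the sex of the mice. Neither of these libraries reads as cells of a single sex. Whether mice were pooled or samples mixed is not given in the sources used here.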
